A study of Drosophila melanogaster with 3 samples.

How the data were processed

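Chromatin from whole wandering third-instar larvae of a mixed-sex transgenic line carrying eGFP fused to the C terminus of Pipsqueak was sonicated, with fragments of 200 to 800 bp per the labels, and precipitated with an antibody against GFP. The 3 samples are biological replicates of 1 group, per the labels. The deposited files are peak lists. Per the text files deposited with the samples, each replicate list and the pooled list hold peaks and background called against a control and served as input for the irreproducible discovery rate (IDR) step, and the optimal list is its output. Each list exists on dm6 and on dm3. The aligner, the peak caller and the IDR threshold are not given in the sources used here, and the control was not analysed here.

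Each entry of a list carries the authors' signal value, whose scale is not stated, the authors' −log10 of the q-value, and a summit offset in bp from the start of the entry, as deposited. The signal value belongs to its own list and was used only to rank, filter or describe peaks within that list. The −log10 q-value reaches a ceiling of 4.30 in the optimal and pooled dm6 lists and was used only to count entries with a q-value of at most 0.01. The pooled and replicate lists are capped at 30000 entries and are not call sets, so each replicate list was reduced to its 9459 entries with the highest signal, the number of optimal peaks (top list). No counts of reads are in the lists, so depth is unknown and intervals for counting error could not be given. The 584 optimal entries that repeat the coordinates of an earlier entry of the list were kept, since their summits differ, and an alternative kept 1 entry per set of overlapping entries.

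Positions were compared with release 6 of the Drosophila genome (NCBI RefSeq) and with Ensembl release 115 gene models, which carry FlyBase release 6.54. No optimal entry on dm6 lay beyond the end of an arm. Transposable elements were left out of the gene models. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Peaks were taken as shared when they overlapped by at least 1 bp, counted in Python, and bedtools 2.31.1 gave the same 7635 peaks in every top list. Replicate errors are SDs over the 3 top lists.

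Summits were assigned in the order promoter (within 500 bp of any annotated start site), 5' UTR, coding exon, 3' UTR, other exon, intron and intergenic, and compared with 1000 random placements within the same arm. Shares per arm were compared with 1000 random draws by arm length. Motifs were sought on either strand in windows reaching 50 bp to each side of the summit and of a point 500 bp to 1 randomly chosen side, with an exact McNemar test across peaks and Benjamini-Hochberg adjustment over 16 motifs. All 6-mers were compared between summit windows and both flanks with Fisher's exact test and Benjamini-Hochberg adjustment over 2080 pairs. The signal of peaks with and without GAGAG was compared with 100000 resamples of the median log2 signal. Tests over peaks treat peaks as units. They are not independent replicates, and their p-values describe these lists, not the spread between animals.

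A gene was called bound with an optimal summit in its span or within 1 kb of it. Bound shares of 19 gene lists were compared with 10000 random lists of protein-coding genes matched on span in 20 length bins (two-sided permutation p, Benjamini-Hochberg over the lists). The smallest p these lists can give is 0.0002, which became 0.00095 after adjustment. Random lists drew genes independently, although neighbouring genes can share summits. Where members of a list lie side by side, its permutation p may therefore be too small. The lists were Hox genes, Polycomb target developmental regulators, Polycomb, Trithorax and GAGA-associated factors, ecdysone synthesis and response, retinal determination and antennal regulators, imaginal disc patterning, Notch pathway and Enhancer of split complex, cell death, Hippo pathway and growth, cytosolic ribosomal proteins, heat shock, chemoreceptors, cuticle proteins, fat body and larval serum, salivary gland glue and Eig71E, muscle structure, neuronal function, germline, and dosage compensation and sex determination. Renamed members were matched through the synonyms of the RefSeq gene table, and every member was found. Windows of 50 kb were counted as dense when they held more summits than the 95th percentile of the fullest window over 1000 random placements.

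Genes were named by a rule fixed before the data were examined, as were the lists, motifs, tests and most of the alternatives. The rule took psq, the genes at the 15 strongest peaks (span holding the summit, or else nearest start site), up to 5 genes with the most summits in each of the 3 densest windows, the 4 bound members with the strongest summit of each list past its test, 2 of every other list, and all Hox genes.

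The tests were tried on simulated data. In simulated windows, 20 of 20 planted 6-mers were recovered among 2080 with 0 false calls. Both simulated sets came from random positions and had like base composition. The trial therefore says nothing about calls that follow from the different composition of real summit and flank windows. Of 200 random gene lists 8 had p under 0.05, and 1 of 100 random placements had a window beyond its limit. Alternatives changed the build, the overlap, the size of the top list, the promoter width, the summit window, the background, the definition of a bound gene, the matching and the window size, took the stronger 50% of the peaks, and left out each replicate in turn. Without a replicate, the optimal peaks were those overlapped by the top lists of both others.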

Results

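Chromatin immunoprecipitation followed by sequencing mapped where Pipsqueak, tagged with eGFP, was bound in whole wandering third-instar larvae of Drosophila melanogaster. Pipsqueak is a BTB-domain DNA-binding protein of the GAGA-associated group, and the tagged protein was precipitated with an antibody against GFP. The animals were a mixed-sex pool of a transgenic line, and the 3 samples were biological replicates of 1 group. The authors deposited a list of 9459 peaks that passed their reproducibility step (the optimal list), a pooled list derived from all 3 replicates, and a list for each replicate. The pooled list and each replicate list held 30000 entries, which included background regions. No read counts or depths were given, so the depth of each sample is unknown, and with 1 group there was no test between conditions. All coordinates are on dm6.

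The psq gene itself, on the plus strand of 2R from 10557888 to 10617280, held the strongest peak of the genome. This peak (2R, 10557423 to 10560770) had its summit at 10558964, in an intron 1076 bp from the nearest psq start site, and ranked 1 in all 3 replicates. Its signal value was 14175, which was 1.81 times that of the strongest peak elsewhere (7829). In all, 32 optimal summits lay within psq or 1 kb of it, against a mean of 4.26 and a maximum of 11 over 1000 random placements (two-sided permutation p = 0.002, the smallest these placements can give). The top lists of the replicates placed 32.3 ± 1.53 summits there (SD, n = 3), and 6 of the 94 strongest peaks of the genome were at psq. Among 615 genes of comparable span, whose median was 2 summits, psq ranked 4 by number of summits. The line is transgenic for tagged psq, per the labels, and whether it carries extra copies of the whole locus is not given in the sources used here. With 1 entry per set of overlapping entries the count was 17.

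**Figure D1:**
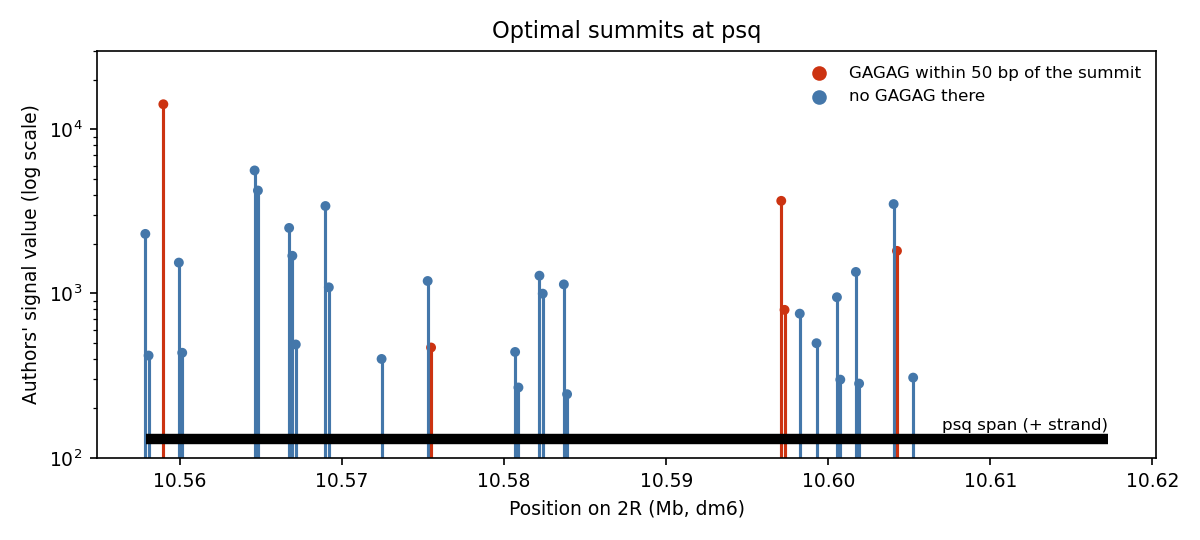
Each line is 1 of the 32 optimal summits at psq, with its position on 2R (Mb, dm6) on the x axis and the authors' signal value on a logarithmic y axis; red marks summits with GAGAG within 50 bp of the summit and the black bar is the span of psq. The highest line, at 14175, stands close to the 5' end of the gene.

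Most optimal peaks were also among the strongest entries of each replicate. The optimal list comes from the same replicates through a reproducibility step, so part of this overlap is built in and random placement is not a fair expectation for it. Of the optimal peaks, 7635 (80.7%) were overlapped by the 9459 strongest entries of every replicate, and 19 by those of none. Random placement within the same arm gave 3.95% on average and at most 4.66% (one-sided permutation p = 0.001, the smallest these placements can give). The share was 56.0% with reciprocal overlap of 50%, 62.7% with summits at most 100 bp apart and 45.4% with top lists of 50% of the size. It fell from 99.8% among the strongest 10% of the optimal peaks to 24.5% among the weakest 10%. Single replicates overlapped 91.1%, 92.4% and 92.4% of the optimal peaks, a mean of 92.0% ± 0.729 (SD, n = 3). Across the 9329 peaks with a matching entry in each replicate, signal ranks correlated at Spearman 0.917 between replicates 2 and 3, 0.811 between replicates 1 and 2, and 0.808 between replicates 1 and 3. These correlations are across peaks, which are not independent replicates. Each optimal peak took the strongest overlapping entry of a replicate, so overlapping optimal peaks could share the same replicate values and enter repeatedly. The replicate 1 list also held fewer entries with a q-value of at most 0.01 (9925) than those of replicate 2 (16596) and replicate 3 (14879).

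The optimal entries had a median width of 520 bp and together covered 3955.6 kb, which is 2.96% of the chromosome arms. Many lay on top of each other: the 9459 entries formed 7590 separate regions, of which 1705 held several entries. The optimal entries were exactly the 9459 entries of the pooled list with the highest signal.

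Pipsqueak was found mainly at promoters and in introns, and hardly at all in coding exons. Of the optimal summits, 4101 (43.4%) lay within 500 bp of an annotated start site, 3.19 times the 13.6% of random placements, and the top lists of the replicates gave 43.4% ± 1.08 (SD, n = 3). Introns held 3742 summits (39.6%), against 39.5% at random (permutation p = 0.881). Coding exons held 23 summits (0.243% against 13.7%) and 3' UTRs held 69 (0.729% against 4.44%). Intergenic sequence held 1319 (13.9% against 27.2%), and 5' UTRs outside promoters held 110 (1.16% against 0.782%). The 95 summits in other exons (1.00% against 0.812%) did not pass the test (permutation p = 0.0579). For promoters, both kinds of UTR, coding exons and intergenic sequence the two-sided permutation p was 0.002, the smallest that 1000 placements can give.

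**Figure D2:**
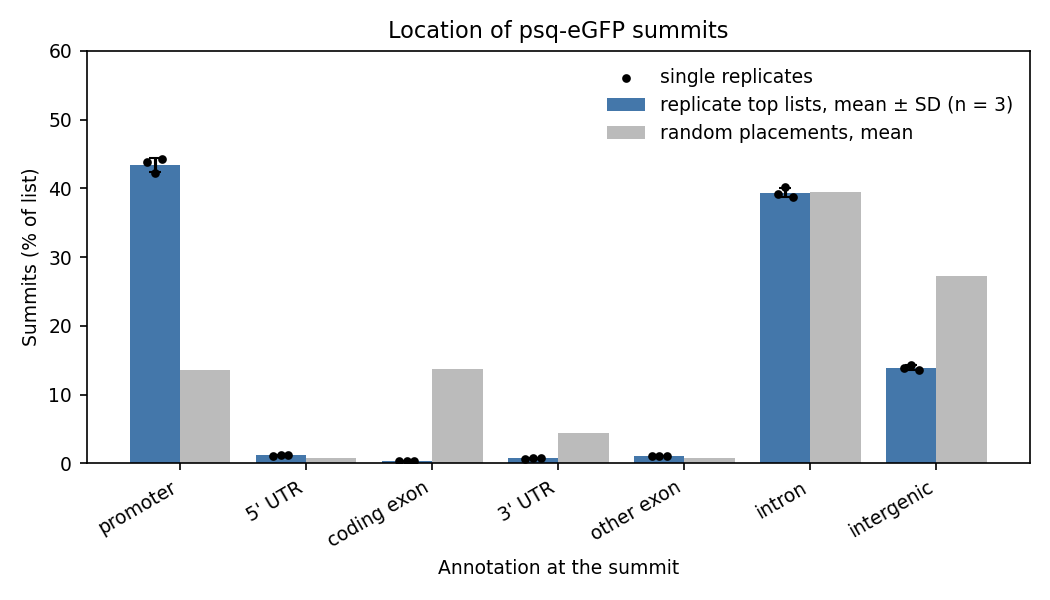
Bars give the percentage of summits in each annotation class for the top lists of the 3 replicates (blue, mean ± SD, black points for single replicates) and for random placements of the optimal summits (grey, mean). Promoters stand at 43.4% against 13.6% at random, and coding exons at 0.328% against 13.7%.

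The X chromosome carried more peaks than its length gives, and the fourth chromosome far fewer. On X there were 1839 peaks (19.4%, or 78.3 per Mb), against 17.1% expected from length (two-sided permutation p = 0.002, the smallest these placements can give) and 17.0% expected from protein-coding start sites. The top lists of the replicates gave 19.4% ± 0.591 on X (SD, n = 3). Arm 3L was also above its length (22.4% against 20.4%, permutation p = 0.002) and 3R was below it (22.2% against 23.4%, p = 0.00799). Arms 2L and 2R were at 17.3% and 18.5%, against 17.2% and 18.4% expected (permutation p = 0.833 and 0.969), but both were below the 18.8% and 20.5% expected from start sites (permutation p = 0.002 for each). The small chromosome 4 had 21 peaks (0.222% against 0.972%, permutation p = 0.002), and 28.1% of its sequence is masked as repeats. Y had 0 peaks (2.47% expected from length and 0.119% from start sites). No dm6 list held an entry on Y, those with background included, so this count was fixed in advance and tests nothing. Because the expectation from length includes Y, the expected shares of the other arms are somewhat low.

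Outside psq, the strongest peaks included ones in the genes of the insulin receptor and of the Hippo pathway kinase Warts. In descending order of signal, they were at CG1910 (7829), 6016 bp from the nearest start site of a protein-coding gene, that of CG4004 (7664), in the overlapping genes CG42245 and MEP-1 (7650), in InR, the insulin receptor gene (7563), in wts, the Warts gene (7454), in crol, a zinc finger gene (7218), in ush, the GATA cofactor U-shaped (7114), and in upSET, a chromatin gene (6371). The next were near Ppa (6319), in CG32772 (6057), near CG13323 (6049), in pum, the translational repressor Pumilio (5947), and in CG3726 (5708). The peak in InR (3R, 21605124 to 21606107) was intronic, 13426 bp from the nearest InR start site, and the peak in wts (3R, 30794442 to 30795380) was intronic as well. The peak at CG1910 (3R, 31747470 to 31748903) lay 140 bp from its start site, whereas the one assigned to CG13323 (2R, 13034966 to 13035674) was intergenic and 11903 bp from the start site of that gene. Of the 15 strongest peaks, 2 were at promoters (CG1910, and the peak assigned to CG4004, which lay at a start site of another annotated gene) and 5 had GAGAG in the window of 50 bp to each side of the summit. None of the 15 ranked below 61 in any replicate.

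GAGAG, the core of the element that Pipsqueak and the GAGA factor bind, was more frequent at summits than in flanks, although most summits lacked it. It was present in 17.0% of windows reaching 50 bp to each side of the summit and in 13.6% of flank windows 500 bp away, a ratio of 1.25 (exact McNemar test across peaks, two-sided, p = 4.43e-11, adjusted p = 2.36e-10 over 16 motifs). The top lists of the replicates gave 17.0% ± 1.47 at summits and 13.9% ± 0.164 in flanks (SD, n = 3), higher at summits in 3 of 3 replicates. The longer GAGAGAG was at 4.31% of summits and 2.46% of flanks (adjusted exact p = 1.54e-11). GGAAG and AGGGA, which have the same bases in another order, were not higher (12.4% against 13.1%, adjusted exact p = 0.230, and 11.4% against 11.4%, adjusted p = 1), but the composition control GAAAG was (25.2% against 21.8%, adjusted p = 9.02e-08). Summit windows were richer in A and T than their surroundings, with a mean GC content of 37.9% against 42.7% in flanks and 42.2% at random positions.

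The highest GAGAG frequency was not at the summit itself. In windows of 51 bp it was 8.85% at the optimal summits and 10.9% at 100 bp to 1 side (exact McNemar p = 1.36e-06), and the same pair was 7.98% and 9.94% in replicate 1, 9.19% and 11.1% in replicate 2, and 9.20% and 11.2% in replicate 3. This comparison was chosen after the data were seen. It was not repeated with 1 entry per set of overlapping entries, although 1705 regions held several entries with separate summits. For GGAAG the optimal list gave 6.18% and 6.06% (exact p = 0.739). AGGGA, the other control with the same bases, gave 5.24% and 5.71% (exact p = 0.168), but in replicate 2 it was lower at the summit as well (4.96% against 6.32%, exact p = 4.76e-05).

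**Figure D3:**
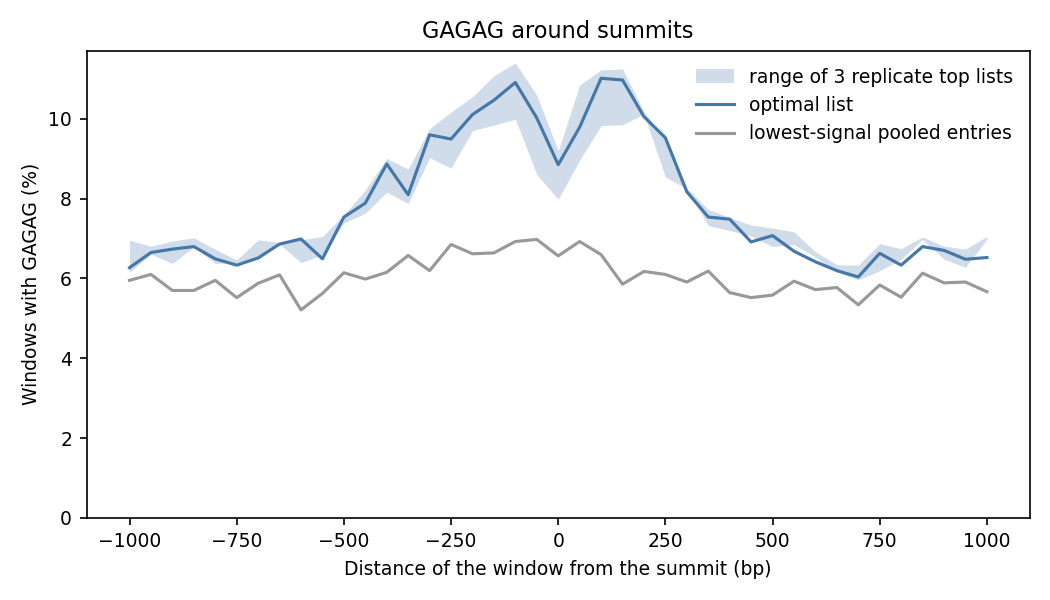
The y axis is the percentage of 51 bp windows with GAGAG on either strand, at the distance from the summit (bp) on the x axis, for the optimal list (blue line), the range of the 3 replicate top lists (shading) and the 9459 pooled entries with the lowest signal (grey). The optimal list is at 8.85% at the summit and at 11.0% at a distance of 100 bp to the right.

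GAGAG was also counted by annotation and by peak strength, without a test between classes. It was at 36.4% of summits in 5' UTRs against 10.9% of their flanks (exact McNemar p = 8.36e-06, 110 peaks), at 16.8% against 13.1% at promoters (p = 3.98e-06) and at 17.9% against 14.9% in introns (p = 0.000428). At intergenic summits it was 13.3% against 12.6% (exact p = 0.636). The strongest 10% of peaks had GAGAG at 22.4% of summits and 15.3% of flanks, and the weakest 10% at 14.4% and 11.6%. There was no steady fall between them, with 16.5% of summits in the second 10% and 17.5% in the eighth. Peaks with GAGAG had a median signal of 387 (1609 peaks) and those without it 360 (7850 peaks), a log2 difference of 0.10 (permutation test, 100000 resamples, two-sided, p = 0.00265). Within the replicates' own top lists the difference was 0.07 ± 0.04 (SD, n = 3). Among the stronger 50% of the peaks the difference no longer passed the test (0.08, permutation p = 0.0630), and without replicate 1 it was 0.07 (permutation p = 0.0408).

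Among the other motifs, the DNA replication-related element TATCGATA was 3.27 times as frequent at summits as in flanks (1.14% against 0.349%, adjusted exact p = 6.75e-10) and the core promoter sequence GGTCACACT 2.30 times (0.486% against 0.211%, adjusted p = 0.00330). Flanks lie at promoters less often than summits may. Against random positions of the same annotation class, chosen after seeing the data, the ratios were 1.93 for TATCGATA (0.592% in that background, Fisher exact test, adjusted p = 0.000111) and 2.00 for GGTCACACT (0.243%, adjusted p = 0.0120). TATAAA was at 17.3% of summits and 11.3% of flanks (adjusted exact p = 2.74e-31). It holds no G or C, and other such sequences rose as much, as AAAATA did (31.2% against 19.9%). The rise of TATAAA therefore cannot be told apart from the AT-rich composition of summit windows. GCCAT, the core of the Pleiohomeotic site, was less frequent at summits (14.04% against 17.2%, adjusted exact p = 1.17e-08). So were AGGTCA, the nuclear receptor half-site sequence (1.56% against 2.38%, adjusted exact p = 0.000164), the E-box CACGTG (0.814% against 1.29%, adjusted p = 0.00330) and the Zelda site CAGGTAG (0.433% against 0.708%, adjusted p = 0.0252). Summit windows were poorer in G and C than flanks, and whether this alone lowers these motifs was not tested. CACACA, TGAGTCA, AACCGGTT and CAGCTG did not pass the exact McNemar test (adjusted p = 0.225, 0.334, 1 and 0.458). CACACA was lower at summits past the test with the stronger 50% of the peaks (9.92% against 11.97%, adjusted exact p = 0.00349), with 1 entry per set of overlapping entries (9.20% against 11.2%, adjusted p = 0.000105) and in windows of 51 bp (5.01% against 6.04%, adjusted p = 0.00463), but higher against positions of the same class. GGAAG was lower past the test without replicate 2 (adjusted exact p = 0.0154), with 1 entry per set (adjusted p = 0.0457) and in windows reaching 100 bp to each side (adjusted p = 0.0214). The call of CAGGTAG was lost without replicate 2 (adjusted exact p = 0.0870), with 1 entry per set (adjusted p = 0.0805), in windows of 51 bp (adjusted p = 0.110) and against the same class (adjusted p = 0.746). That of GGTCACACT was lost with the stronger 50% of the peaks (adjusted exact p = 0.394) and in windows of 51 bp (adjusted p = 0.0983). Over their alternatives the adjusted exact p ran from 0.0149 to 0.746 for CAGGTAG and from 4.05e-10 to 0.394 for GGTCACACT.

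Of all 2080 pairs of 6-mers, 40 were more frequent at summits than in flanks and 302 less frequent (Fisher's exact test, Benjamini-Hochberg adjusted p under 0.05 and a ratio of at least 1.5). The former were mostly AT-rich: 15 held no G or C, led by AAAATA at 31.2% of summits against 19.9% of flanks, and 4 held GAGA. The less frequent ones were rich in G and C, with a mean of 4.28 such bases, and 0 of them had at most 1. Against random positions of the same annotation class, a background chosen after seeing the data, 26 were more frequent, of which 9 held GAGA and 0 lacked G and C. AGAGAG then led, at 9.29% of summits against 3.86%. AT-rich 6-mers stayed more frequent at summits but fell below the ratio of 1.5, as AAAATA did (31.2% against 22.3%, ratio 1.40, adjusted exact p = 1.06e-40). Counts of 6-mers moved with the window and background, from 14 with windows reaching 100 bp to each side of the summit to 67 with windows of 51 bp, and there were 77 with 1 entry per set of overlapping entries.

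Of 13968 protein-coding genes, 5222 (37.4%) had an optimal summit within their span or 1 kb of it, and are called bound here. Unless stated otherwise, numbers of summits at a gene count overlapping entries separately. Of the 19 gene lists fixed beforehand, 4 had more bound genes than random lists matched on gene length, and 3 had fewer.

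Ribosomal protein genes stood out most by number. Of 92 genes for cytosolic ribosomal proteins, 69 (75.0%) were bound, against 27.4% in random lists (permutation test, adjusted p = 0.00095, the smallest these lists gave), and the replicates gave 74.6% ± 2.51 (SD, n = 3). By start sites, 72.8% of them had a summit within 1 kb of a start site. The strongest summits were at RpL31 (signal 1780), RpL22 (1091), RpS19b (1039) and RpS27 (1039). The RpL31 summit lay past the 3' end of the gene, 1675 bp from its start site and at a start site of another gene. The RpS19b summit lay 899 bp upstream of RpS19b, in an intron of another gene. The RpS27 summit, at 25247511 on 3R, lay 3 bp from the start site.

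Most genes of the Hippo and Notch pathways were bound. Of 18 Hippo pathway and growth genes, 17 (94.4%) were bound against 56.7% at random (permutation test, adjusted p = 0.00304; replicates 92.6% ± 3.21, SD, n = 3). They included wts, crb, the apical polarity gene crumbs (signal 2407 at 24296072 on 3R, intronic), CycE, which encodes Cyclin E (1975), and ex, which encodes the upstream Hippo regulator Expanded (1891, with 10 summits). Of 21 genes of the Notch pathway and the Enhancer of split complex, 17 (81.0%) were bound against 41.4% (adjusted permutation p = 0.00095; replicates 77.8% ± 5.50). The genes of the complex are neighbours and not independent, so this p may be too small. N, the Notch receptor gene on X, held 14 summits, with the strongest at 3136486 in an intron (2873). The others named by the fixed rule were numb (1825), neur (1677) and mam (1108, with 16 summits).

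Of 28 genes of ecdysone synthesis and response, 22 were bound (78.6% against 55.9%, permutation test, adjusted p = 0.0483; replicates 79.8% ± 2.06, SD, n = 3). EcR, the ecdysone receptor gene on 2R, held 31 summits, the strongest 175 bp from a start site (signal 5239, rank 17 of the genome). Eip75B, an early ecdysone-induced nuclear receptor gene on 3L, held 37, the strongest intronic (4775). Hr3 (4104) and Hr39 (3385), also nuclear receptor genes, had their strongest summits within 500 bp of an annotated start site, which for Hr39 was not its own, since the summit lay 650 bp from the nearest Hr39 start site. The genes named here belong to the response. Of the genes for ecdysone synthesis, dib, phtm, sad, spo and nvd had 0 summits and shd had 4, and these were chosen after their values were seen. When a gene counted as bound only with a summit within 1 kb of a start site, the ecdysone list was at 57.1% against 43.3% and its call was lost (adjusted permutation p = 0.335; 0.0242 to 0.335 over its alternatives).

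Chemosensory, cuticle and neuronal genes were bound less often. Only 11 of 179 chemoreceptor genes (6.15% against 33.2%) and 7 of 117 cuticle protein genes (5.98% against 25.4%) had a summit (permutation test, each adjusted p = 0.00095), and the replicates gave 6.52% ± 0.645 and 6.55% ± 1.78 (SD, n = 3). Without replicate 1 the share of cuticle genes was 3.42%. The bound chemoreceptor genes with the strongest summits were Ir94h (609), Or85f (582), Ir68b (577) and Gr32a (471), and the bound cuticle genes were led by Cpr72Eb and Cpr72Ea, which share 1 summit (499), Cpr51A (377) and Cpr12A (347). The summits of Or85f and Ir68b lay past the 3' ends of these genes, at start sites of other genes. Of 22 genes of neuronal function, 7 were bound (31.8% against 62.5%, adjusted permutation p = 0.0228; replicates 27.3% ± 4.55). Those 7 included Syx1A, with 1 of the strongest peaks of the genome at its promoter (5128, rank 19), Syn (2439), elav (1481) and ChAT (433). The neuronal call was lost with summits near start sites only (adjusted permutation p = 0.0646) and with the stronger 50% of the peaks (adjusted p = 0.0755; 0.00836 to 0.0755 over its alternatives).

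**Figure D4:**
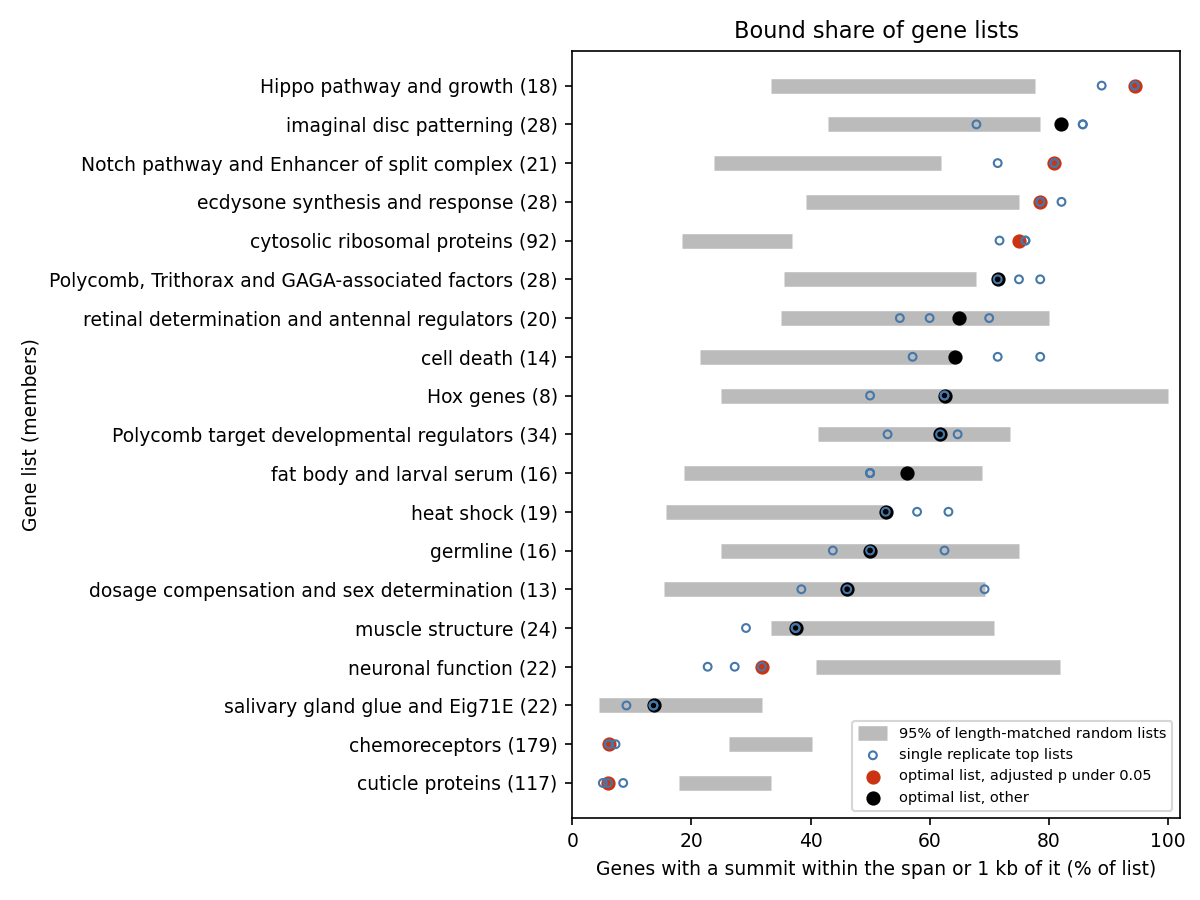
Each line is a gene list, with its number of members; the x axis is the percentage of members with a summit. Filled points are the optimal list (red where the adjusted p is under 0.05), open circles the top lists of the 3 replicates, and grey bars the central 95% of length-matched random lists. Hippo pathway genes lie highest at 94.4%, and cuticle protein genes lowest at 5.98%.

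The regulators with which Pipsqueak is grouped did not pass the main test. Of 28 Polycomb, Trithorax and GAGA-associated genes, 20 (71.4% against 51.4%) were bound (permutation test, adjusted p = 0.0925), led by psq itself and ash1 (4973, at a promoter by the 3' end of the gene). The list passed when only summits within 1 kb of a start site counted (67.9% against 42.7%, adjusted permutation p = 0.0337), with the stronger 50% of the peaks (adjusted p = 0.000760) and without any 1 replicate (adjusted p from 0.0218 to 0.0261). The tagged gene psq counted as a bound member in each of these settings. Over all its alternatives the adjusted permutation p ran from 0.000760 to 0.157. Imaginal disc patterning genes, 23 of 28 bound (82.1% against 60.8%, adjusted permutation p = 0.0584), with bowl (2143) and ds (1763) the strongest, passed without replicate 1 (adjusted p = 0.0212) and with matching on neighbouring genes (adjusted p = 0.00443; 0.00443 to 0.698 over its alternatives).

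Hox genes and Polycomb targets did not pass the main test in either direction. Of 8 Hox genes, 5 had a summit (62.5% against 64.3%, permutation test, adjusted p = 1), all of them away from start sites: within 1 kb of a start site 0 of the 8 were bound, against 48.5% at random (adjusted p = 0.0337). Hox genes lie close together in groups on 3R, so they are not independent and this p may be too small. Antp held 14 summits, the strongest at 6914562 on 3R in an intron (944). Abd-B (560), abd-A (272) and Scr (195) had 1 summit each and Ubx had 4 (254 at the strongest). The summits at Ubx and Scr depended on the replicates, since Ubx had 0 without replicate 1, 1 without replicate 2 and 2 without replicate 3, and Scr had 0 without any 1 of them. Without replicate 1 the bound share of Hox genes was 37.5%. At lab, pb and Dfd there were 0. Of 34 Polycomb target developmental regulators, 21 were bound (61.8% against 56.9%, adjusted permutation p = 0.867), with eyg (834) and dac (537) the strongest. The direction was not stable: the share was 20.6% against 39.5% with the stronger 50% of the peaks (adjusted permutation p = 0.0777), 41.2% against 50.9% without replicate 2 and 44.1% against 50.7% without replicate 3.

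The remaining lists did not pass the permutation test either. For retinal determination and antennal regulators 13 of 20 were bound (adjusted permutation p = 0.867), with so (2699) and eyg the strongest. For cell death it was 9 of 14 (adjusted permutation p = 0.243), with hid (2437) and Dcp-1 (2012). For heat shock it was 10 of 19 (adjusted permutation p = 0.236), with Hsp27 (4030, at its promoter) and Hsp83 (1572); Hsp27 had 2 summits, and 1 without replicate 2 or replicate 3. For fat body and larval serum it was 9 of 16 (adjusted permutation p = 0.559), with Lsd-2 (1241) and Lsp1gamma (1102), and for muscle structure 9 of 24 (adjusted p = 0.344), with Tm1 (1409) and Mlc2 (1158). For salivary gland glue and Eig71E genes it was 3 of 22 (adjusted permutation p = 1), with Sgs5 and Sgs5bis sharing a summit (277). For germline genes it was 8 of 16 (adjusted permutation p = 1), with cup (2266) and orb (793), and for dosage compensation and sex determination 6 of 13 (adjusted p = 1), with fru (1650) and Sxl (668). The strongest summits of so and cup lay 10197 and 9299 bp from their own nearest start sites, and those of Lsp1gamma and Mlc2 past the 3' ends. Each of these lay within 500 bp of an annotated start site of another gene.

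Some windows held more summits than random placement gives, although most summits lay outside them. Of 2680 windows of 50 kb, 58 held more than 14 summits, the limit set by random placement, and together they held 1094 summits (11.6%) in 2.16% of the windows. The densest by number of summits, on 3L from 2800001 to 2850000, held 31, all at Tet. This gene encodes the fly homologue of the TET dioxygenases and held 43 summits over its whole span. The next, on 3R from 16200001 to 16250000, held 30, of which 17 were at tara, a transcriptional coregulator gene, and 1 was shared by CG31287 and mtSSB. A window on 3R from 30250001 to 30300000 held 29, of which 13 were at heca. The order depends on overlapping entries being counted separately. In separate regions these windows held 18, 19 and 18, and the window at E2f1 and InR, with 28 summits, held 20. The number of such windows was 36 with the stronger 50% of the peaks and 33 with 1 entry per set of overlapping entries.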

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

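The tests of overlapping entries, extra copies, weak entries and base composition in this part were chosen only after the result was seen. The group of 3 samples was too small for a test of outlying samples. The first result below comes from entries that the comparisons did not use. Outside the optimal list, 4958 entries of the pooled list had a q-value of at most 0.01, with signal values from 121 to 191. GAGAG was at 16.2% of their summits and 12.4% of their flanks (exact McNemar p = 4.58e-08), and 37.6% of them were at promoters. On dm3, 4 pooled entries with a q-value of at most 0.01 lay on sequences outside the chromosome arms, as did 1 entry of the dm3 optimal list, which served only as an alternative.

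The number of summits at psq could reflect overlapping entries that were counted separately, or extra copies of the locus, if the tagged line carries them. With 1 entry per set of overlapping entries psq held 17 summits, above the maximum of 10 over random placements of those entries, which argues against the former as the whole cause. Among genes of comparable span, 3 others (Tet, Eip75B and sbb, with 43, 37 and 36 summits; sbb was chosen after its values were seen) had at least as many as the 32 at psq without being tagged. Extra copies and binding of Pipsqueak to its own gene cannot be told apart, because no untagged line or input was analysed here. No biological explanation was tested.

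The low share of summits with GAGAG (17.0%) could come from summits placed away from the motif, from weak entries, or, for its excess over flanks, from base composition. Over whole entries, 57.6% held GAGAG against 44.0% of class-matched windows of the same widths, an excess of 13.6 percentage points (95% bootstrap interval 12.2 to 14.9), under the 20 points set beforehand as the bound. The background left room for at most 56.0 points, so the 50 points set for this cause were nearly out of reach, but GAGAG of their own in 50% of the entries would still add 28.0. The 13.6 points found argue against GAGAG of their own, at the summit or away from it, in 50% of the entries. How much of that excess lies at misplaced summits stays open. At the summits the excess over class-matched windows was only 5.63 points, and GAGAG was more frequent 100 bp away (10.9% against 8.85%). Among the 10% of peaks with the highest signal 22.4% held it (exact interval 19.8 to 25.2), so weak entries are not the whole cause. GGAAG, with the same bases, had a ratio of summit to flank share of 0.949 (95% bootstrap interval 0.875 to 1.02) against 1.25 for GAGAG (1.17 to 1.34), which argues against base composition alone. GAAAG, a control with more A, was also higher at summits (25.2% against 21.8%, a ratio of 1.16, adjusted exact p = 9.02e-08, in 3 of 3 replicates), so a part played by A-rich purine sequence stays open. Binding through other sequences or partners stays open and was not tested.

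The excess of peaks on X could come from a lower share of repeat sequence on that arm or from more GAGAG there. Unmasked length gave an expected 17.1% of peaks on X (95% of draws 16.4 to 17.8), below the 19.4% observed. Full length gave 17.1% as well. Of the sequence of X 21.1% is masked as repeats, against 18.1% on 2L, 20.2% on 2R, 21.3% on 3L, 19.5% on 3R, 28.1% on 4 and 53.3% on Y. These values argue against a lower share of repeat sequence as a cause of the excess. Of the 7850 peaks without GAGAG within 50 bp of the summit, 19.3% lay on X, above the 16.3 to 18.1 expected from length. Of the peaks with it, 20.1% did. This comparison cannot decide. Most peaks lack GAGAG in that window, so their share on X had to lie near that of all peaks. Over whole entries 57.6% held GAGAG, and its frequency was not counted per arm. More GAGAG on X stays open as a cause, and no biological explanation was tested.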

How the results depend on the processing

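Alternatives with 1 entry per set of overlapping entries, class-matched background, start sites as the expectation for X, psq left out, and all those for psq, the other motifs and single genes were chosen after seeing the data. The optimal peak count, the share of peaks in every replicate, the promoter, X and GAGAG shares, the number of motifs and the number of gene lists past their tests stayed on the same side of their thresholds, or within 1.5 times, under every alternative run, although the share in every replicate ran from 45.4% with top lists of 50% of the size to 98.7% with the stronger 50% of the peaks, and the lists and motifs behind those numbers were not always the same. Their calls rest on the authors' threshold, and since depth is unknown its effect could not be measured. Restriction to the 6 main arms removed no peak and tests nothing. The peaks kept without a replicate are part of the optimal list, so for the peak count that alternative only restates the overlap with the other top lists. The mean rank correlation was 0.845, and from 0.808 to 0.917 without a replicate, the highest being without replicate 1. With the stronger 50% of the peaks the signal difference by GAGAG was 0.0788 on the log2 scale (permutation p = 0.0630), with fewer peaks tested, and 36 windows were dense instead of 58. With 1 entry per set of overlapping entries there were 77 enriched 6-mers instead of 40, 33 dense windows and 17 summits at psq. Enriched 6-mers numbered 67 with windows of 51 bp, 14 with windows reaching 100 bp to each side, 26 against the lowest-signal entries and 26 against the same annotation class. CACACA, lower at summits than in flanks (10.5% against 11.2%, past the test only with the stronger 50% of the peaks, 1 entry per set or windows of 51 bp), was higher than in positions of the same class (10.5% against 8.62%, Fisher exact test, adjusted p = 2.18e-05). Among values of single lists, motifs and genes under an alternative, 14 newly passed a test, 9 no longer passed and 46 counts of summits at a gene moved by over 1.5 times. For the shifts in windows, psq, 6-mers and CACACA the cause was not tested.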

Other observations

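Outside the named genes, the genes with the most summits included sbb (36), kirre (32), CG1677 (25), E2f1 (24), Tlk (24), jing (24) and tou (24). They were chosen after their values were seen. Windows with an excess of summits also lay at Psc and Su(z)2, neighbouring Polycomb group genes on 2R (24 summits from 12950001 to 13000000), and at E2f1 and InR on 3R (28 from 21600001 to 21650000). A summit lay within 500 bp of a start site for 27.4% of 13968 protein-coding genes, 21.9% of 32 snRNA genes, 12.2% of 3289 noncoding RNA genes, 7.59% of 290 tRNA genes, 7.06% of 269 snoRNA genes, 3.64% of 330 pseudogenes and 0 of 99 rRNA genes.

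A hypothesis drawn from the gene lists was that families of broad use may be bound more often than families of narrow use. It was tested on 6 families chosen after seeing those lists, with the direction of each written before its values were seen, and 4 of the 6 differed from length-matched random lists in that direction, fewer than the 5 set as the bound, so it stays open. Mitochondrial ribosomal protein genes were bound at 41 of 73 (56.2% against 22.5%, permutation test, adjusted p = 0.0008, the smallest these lists gave) and aminoacyl-tRNA synthetase genes at 20 of 33 (60.6% against 40.4%, adjusted p = 0.0423). Odorant-binding protein genes were at 1 of 51 (1.96% against 22.1%) and cytochrome P450 genes at 12 of 85 (14.1% against 36.7%), both with adjusted permutation p = 0.0008. Proteasome subunit genes did not differ by the test (15 of 48, 31.2% against 28.9%, adjusted permutation p = 0.816), and Jonah serine protease genes, at 0 of 16 against 21.3%, narrowly missed it (adjusted p = 0.0521).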
